A study of Mus musculus with 2 samples.

How the data were processed

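RNA was measured in 2 populations of cells sorted from ventral skin of 7-day-old C57BL/6 mice, with 1 library per group. Per the labels' protocols, minced skin was digested with dispase and collagenase and filtered. Cells were stained with a polyclonal antibody against ZIP10 or with normal rabbit IgG, then with a fluorescent antibody against rabbit IgG and the viability dye 7-AAD, and ZIP10-positive and ZIP10-negative cells were sorted. Per the labels' protocols, libraries were made from 10 ng of total RNA with a NEBNext Ultra RNA kit and sequenced on an Illumina HiSeq with single reads of 50 bases. The labels do not name the number of animals, any pooling, or a sort on markers of single cell types.

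The authors deposited a table of RPKM values, with 1 value per gene symbol and library. The unit comes from the table's own name, and the values are not whole and sum to 703748 in the ZIP10-positive and 685692 in the ZIP10-negative library. The submitters' processing notes name cutadapt, TopHat, Cufflinks and the mouse build mm9. Their versions, order and settings, the annotation, and whether counting used strand are not given in the sources used here. Genes that overlap or share near-identical sequence, such as globins, hair keratins, keratin-associated proteins, Lyz1 and Lyz2, stefins and ribosomal protein genes with pseudogenes, can share reads, and their values are uncertain to that extent. The reference used here is GRCm38 with GENCODE vM21, a different build, so no coordinates are given and it served only for names and transcript lengths. Of the 23233 symbols, each listed once, 20645 matched a symbol of the reference gene table and 22994 a symbol or synonym.

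Depth was recovered in part from the ratios between the values of the 2 libraries. If whole reads were counted, the values of a gene in the 2 libraries stand in a ratio of whole numbers times a fixed number, here 0.975. Among 1352 genes at 1 RPKM or less in both libraries, 70.1% had such a ratio with whole numbers up to 20, at a tolerance of 0.0012%, against 1.48% after random rescaling. This fixed number was searched for only near equal depth, and a whole multiple of it could pass the same check. On that basis the depth ratio of the ZIP10-positive to the ZIP10-negative library was 1.03. Absolute depth was estimated from 682 genes with 1 annotated transcript, of which 26.5% lay within 1.4% of the most frequent value. This gave about 2.78e+06 reads in the ZIP10-positive and 2.71e+06 in the ZIP10-negative library and rests on lengths from another annotation, with an assumed offset of 199 bases. On a 2000-base transcript 1 read is worth 0.205 RPKM and 3 reads 0.614 RPKM; on 1000 bases these are 0.46 and 1.38 RPKM. Exact Poisson 95% intervals on 2000 bases are 0.332 to 2.39 RPKM at 1 RPKM and 91.3 to 109 RPKM at 100 RPKM. The interval for the Slc39a10 ratio is an exact binomial one from the smallest whole read numbers that give its ratio, 109 and 24. The true numbers may be a multiple of these. Read numbers from the estimated depth and annotated lengths are given beside them, but fall below that minimum. Reads carry no molecular identifiers, so all intervals cover counting error only.

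Values were compared as log2((positive + 1)/(negative + 1)) with a pseudocount of 1, which understates the change of low genes. Genes with a value of 1 or more in at least 1 library were compared, 12249 in all, of which 9620 reached 1 in both. With 1 library per group there is no test and no p-value, and genes 2-fold or more apart were counted by size alone. The median log2 ratio of the 9620 genes, without a pseudocount, was taken as the median gene, and values relative to it were computed after dividing this shift between the libraries. Across the 12249 genes Pearson's r was 0.84 and Spearman's rho 0.79, and genes are not independent replicates.

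Before the data were examined, 28 gene lists for cell types of skin, follicle compartments and processes were fixed from general knowledge, together with the rules for naming genes. Named are Slc39a10, the 12 highest and 12 lowest ratios among genes at 10 RPKM or more in a library, and up to 4 of the most abundant members of each list, with all measured zinc transporters and metallothioneins; not every gene under the rule is printed, and 1 of the 12 lowest is not reported here. For each list the median log2 ratio was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. These random lists were not matched on transcript length. Lists of fewer than 5 measured members are given as values. Psmg4, Ndufaf3 and the genes of the ranking without small RNA entries were named after their values were seen. In addition 5 lists were written after the data were seen, for neutrophils, Fc gamma receptors, interferon-stimulated genes, cytotoxic T or NK cells and T-lineage genes.

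The analysis used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. It was tested on simulated data for the comparison of the 23233 genes, with a shift of 1 on the log2 scale and 4-fold changes. The shift came back as 0.98. After scaling to the median gene, 99% of raised and 100% of lowered genes were recovered, and 4.55% of unchanged genes passed the size rule. The changed genes were drawn from genes at 5 RPKM or more in both libraries, and the simulated noise was counting error only. These rates do not cover the counts as deposited, which were not scaled to the median gene. Of 200 unchanged lists, 3% lay in the upper or lower 2.5% of matched lists. The simulated genes varied independently, so this share does not cover lists whose genes vary together.

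Alternatives tried were pseudocounts of 0.1 and 5, no filter, a minimum of 5 RPKM, genes above 0 in both libraries, a 4-fold rule, unmatched random lists, and scaling to the median gene, to a sum of 1000000, or to the sum outside the 50 most abundant genes of either library. Chosen after the data were seen were the scaling without globin genes and Rn45s and the counts without the 724 microRNA and small nucleolar RNA entries. Sequence, isoforms and reads were not analysed here.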

Results

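The data set compared skin cells that stained with an antibody against the zinc importer ZIP10 with cells that did not. Ventral skin of 7-day-old C57BL/6 mice was dissociated, stained with an antibody against ZIP10 and separated by flow cytometry into ZIP10-positive and ZIP10-negative cells. The sample titles call both populations hair follicle cells, while the protocol describes a suspension of ventral skin. Polyadenylated RNA of each population was sequenced as 1 library, so there are 2 libraries, no replicate and no test. Differences below describe these libraries, and values are in RPKM, read numbers scaled by transcript length and library size, as deposited. The table lists 23233 genes, of which 14342 had a value above 0 in the ZIP10-positive library and 13558 in the ZIP10-negative library. A depth of about 2.78e+06 reads in the ZIP10-positive library and 2.71e+06 in the ZIP10-negative library was estimated. It came from whole-number ratios of the values and annotated lengths of 682 genes with 1 transcript. Only 26.5% of these genes lay within 1.4% of the most frequent depth. At that depth a gene with a 2000-base transcript at 10 RPKM rests on 48.8 reads, with an exact Poisson 95% interval of 7.42 to 13.3 RPKM that covers counting error only.

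Slc39a10, which encodes ZIP10, stood at 49.4 RPKM in the ZIP10-positive and 11.1 RPKM in the ZIP10-negative library. The ratio was 4.43, with an exact 95% counting interval of 2.83 to 7.21 from the fewest whole reads that give it, 109 and 24. The estimated depth and the median annotated transcript length, 565 bases, gave about 50 and 11 reads and an interval of 2.28 to 9.45. These read numbers lie below the fewest that give the ratio. If whole reads were counted, that length or depth cannot hold for this gene. Relative to the median gene Slc39a10 was 2.25-fold higher, and its log2 ratio was 0.79 with scaling to genes outside the 50 most abundant and 0.72 without globin genes and Rn45s. Because the cells were sorted with an antibody against this protein, the value checks the labels and is not a finding.

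Most genes had higher values in the ZIP10-positive library. Of 12249 genes with at least 1 RPKM in a library, 5405 were at least 2-fold higher and 435 at least 2-fold lower in ZIP10-positive cells, on the log2(RPKM + 1) scale. The median gene with at least 1 RPKM in both libraries had a log2 ratio of 0.98, a ratio of 1.97. Relative to that median gene the split was 1799 higher and 1398 lower, or 56.3% higher in place of 92.6%. Scaling each library to its genes outside the 50 most abundant gave 1188 higher and 2151 lower, or 35.6% higher, and moved the zero point by 1.33. Leaving out globin genes and Rn45s, a scaling chosen after the data were seen, gave 1101 higher and 2352 lower, or 31.9% higher, and moved it by 1.39. Globin genes made up 59.4% of the RPKM sum of the ZIP10-negative library and 3.46% of that of the ZIP10-positive library. Such a sum is scaled by transcript length and is no share of reads. Globin reads were roughly estimated at 16.0% and 0.952% of the reads, respectively, which accounts for a log2 shift of 0.24. Rn45s, the ribosomal RNA precursor, stood at 27537 and 20264 RPKM, respectively. Of 140 named genes, 34 turned from higher to lower relative to the median gene, and 52 did so with scaling to genes outside the 50 most abundant. For these reasons each gene group is given relative to the median gene, and by its percentile among 10000 random lists of equal size and similar expression. Counts of list members higher or lower, as deposited or relative to the median gene, are of members at least 2-fold apart. A single gene or list median said to turn lower fell below 0 by any amount.

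**Figure D1:**
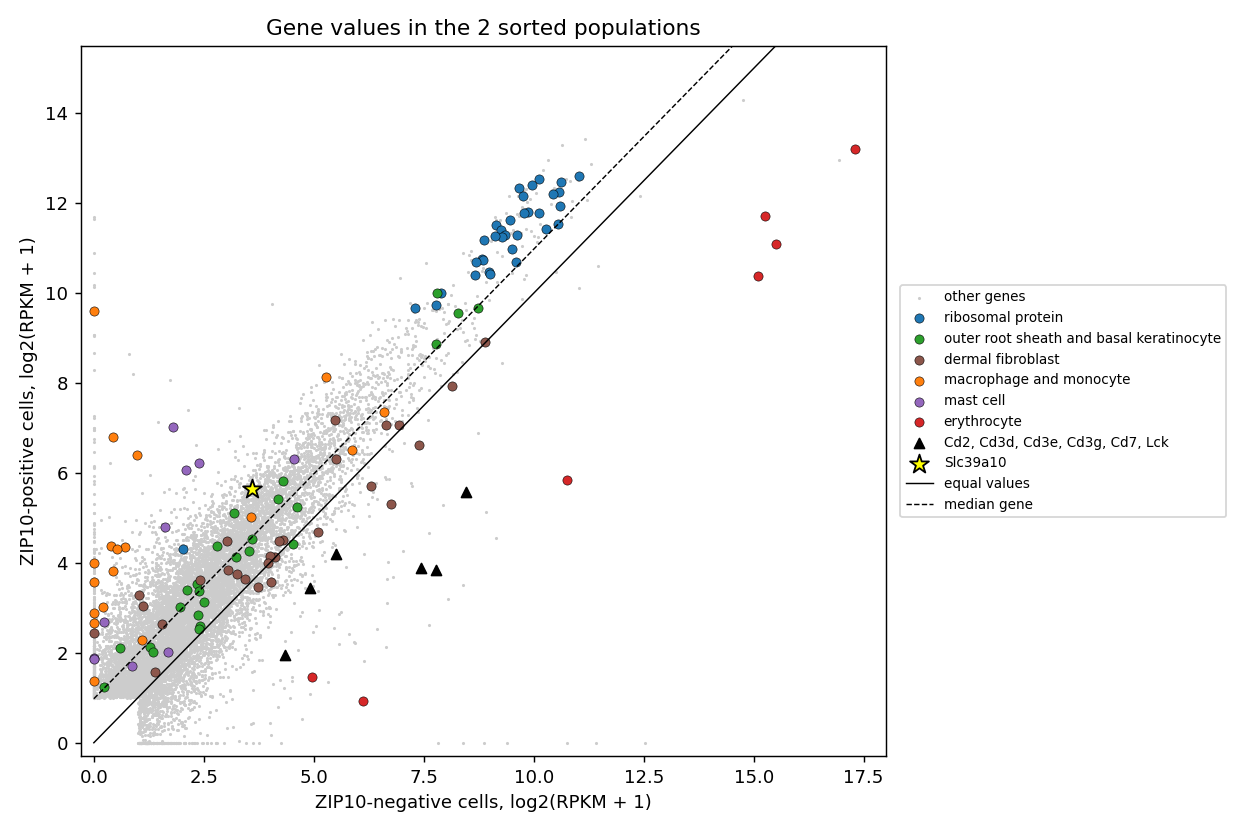
Each point is a gene, with log2(RPKM + 1) in ZIP10-negative cells on the x axis and in ZIP10-positive cells on the y axis; the solid line marks equal values and the dashed line the median gene, at a log2 ratio of 0.98. Macrophage (orange), mast cell (purple) and ribosomal protein genes (blue) lie mostly above the dashed line, while erythrocyte genes (red) and the T-lineage genes Cd2, Cd3d, Cd3e, Cd3g, Cd7 and Lck (triangles) lie below both lines.

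Genes of macrophages and monocytes were far higher in ZIP10-positive cells. Of 18 measured members 16 were at least 2-fold higher and none lower, and 14 remained 2-fold higher relative to the median gene. Their median log2 ratio was 3.12, or 2.62 relative to the median gene, at percentile 100 of the matched lists. Tyrobp, an adaptor of myeloid receptors, stood at 279.8 RPKM against 37.6 RPKM. Lyz2, the lysozyme of myeloid cells, stood at 772 RPKM and was listed at 0 in ZIP10-negative cells. A value of 0 in this table can be a failed estimate, as the broadly expressed Psmg4 and Ndufaf3 were also listed at 0 there, against 69.5 and 24.97 RPKM. Of the 18 members 6 were listed at 0 in ZIP10-negative cells, and the 12 above 0 in both libraries had a median of 2.54 relative to the median gene, with 10 at least 2-fold higher as deposited. Fcer1g, at 163 and 95.7 RPKM, and Laptm5, at 90.3 and 57.6 RPKM, were less than 2-fold apart and lay below the median gene.

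Mast cell genes had the same direction, with 8 of 10 measured members at least 2-fold higher and none lower, and 7 higher relative to the median gene. The median log2 ratio was 2.18, or 1.77 relative to the median gene, at percentile 100. The mast cell protease genes Tpsb2, Cma1 and Mcpt4 stood at 129, 73.7 and 65.8 RPKM against 2.499, 4.22 and 3.28 RPKM. Srgn, the granule proteoglycan serglycin, stood at 78.3 against 22.6 RPKM. In this list 2 members were listed at 0 in ZIP10-negative cells, and the other 8 had a median of 2.18 relative to the median gene, with 6 at least 2-fold higher as deposited. The macrophage and mast cell medians stayed above 0 under each scaling tried.

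Other leukocyte genes divided into opposite groups. Of 21 measured members of the T cell, Langerhans cell and other leukocyte list, 9 were at least 2-fold higher and 8 lower, and relative to the median gene 7 were higher and 9 lower. H2-Ab1, a class II antigen-presenting chain, stood at 399 RPKM against 48.0 RPKM. S100a8, a calcium-binding protein of myeloid cells, stood at 865 against 15.7 RPKM, and its partner S100a9 at 530.01 RPKM against a listed 0. Cd3g, a chain of the T cell receptor complex, was 7.49-fold lower, at 46.9 RPKM against 352 RPKM. The median of the whole list was 0.46 as deposited, at percentile 0.08 but 4.71 among lists not matched on expression, and -0.51 relative to the median gene, so its sign follows the scaling.

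Erythrocyte genes were lower in ZIP10-positive cells, in 7 of 7 measured members and under every scaling tried. The median log2 ratio was -4.42, or -5.40 relative to the median gene, at percentile 0. The alpha-globin gene Hba-a1 stood at 9426 RPKM in ZIP10-positive and 160696 RPKM in ZIP10-negative cells, and Hba-a2 at 1330 and 35178 RPKM. The beta-globin genes Hbb-b1 and Hbb-b2 stood at 3380 and 2182 RPKM against 39407 and 46657 RPKM. Reads of near-identical globin genes can be divided between copies, so single values within these pairs are uncertain.

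Basal keratinocyte genes were not set apart from genes of similar expression. In the outer root sheath and basal keratinocyte list 12 of 25 measured members were at least 2-fold higher and none lower, with 2 higher and 1 lower relative to the median gene. The list median of 0.99, at percentile 44.1, became 0.15 relative to the median gene and turned to -0.15 with scaling to genes outside the 50 most abundant. Krt5, a keratin of the basal layer, stood at 1021 RPKM against 222 RPKM and stayed higher under every scaling. Its partner Krt14 stood at 758 against 311 RPKM and Krt15 at 466 against 219.9 RPKM, and both turned lower, to -0.042 and -0.24 on the log2 scale, with scaling to genes outside the 50 most abundant. Krt17 stood at 812 against 428 RPKM, which is close to the median gene and lower relative to it, by a log2 ratio of -0.054.

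Targets of the transcription factor p63, a regulator of epidermal development, gave a similar picture. Of 22 measured members 11 were at least 2-fold higher and none lower, and relative to the median gene 2 were higher and 2 lower. Their median was 0.98 at percentile 49.4, and it turned from 0.10 relative to the median gene to -0.17 with scaling to genes outside the 50 most abundant. Perp, a desmosomal protein, stood at 387 against 81.8 RPKM, and Cdh3, which encodes P-cadherin, at 55.8 against 18.6 RPKM. The list shares Krt5, Krt14, Cdh3 and other members with the basal keratinocyte list, so these lists are not independent.

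Hair follicle stem cell genes had 9 of 16 measured members at least 2-fold higher and none lower, with 1 higher and 1 lower relative to the median gene. The median was 1.08, at percentile 81.6. It was 0.28 relative to the median gene and turned to -0.031 when globin genes and Rn45s were left out of the scaling. Lhx2, a transcription factor of follicle stem cells, stood at 19.7 against 6.01 RPKM, and Fst, the activin antagonist follistatin, at 60.9 against 35.6 RPKM, which turned lower relative to the median gene. Ltbp1, a binding protein of latent TGF-beta, stood at 46.5 against 65.1 RPKM. Among companion layer and wound-type keratins 4 of 6 were at least 2-fold higher and none lower, with a median of 1.16 at percentile 45.9, and 2 were higher and none lower relative to the median gene. Krt16 stood at 60.2 against 24.9 RPKM and Krt75 at 34.4 against 15.7 RPKM; both, like the list median at -0.12, turned lower with scaling to genes outside the 50 most abundant. Krt79 stood at 174 against 101 RPKM and turned to -0.54 there, and Krt17, a member of this list too, to -0.40.

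Inner root sheath genes lay near the median gene, and genes of the hair matrix and shaft below it. In the inner root sheath list 4 of 12 were at least 2-fold higher and none lower, with a median of 0.87 at percentile 26.4. Relative to the median gene 1 was higher and 1 lower, and the median was -0.027, so its sign follows the scaling. Krt71 stood at 296 against 93.3 RPKM, Krt28 at 179.9 against 95.3 RPKM, Krt25 at 96.7 against 98.0 RPKM and Krt27 at 48.1 against 46.8 RPKM; Krt28 and Krt27 turned lower relative to the median gene. In the hair matrix and shaft list 5 of 22 were at least 2-fold higher and 1 lower, with 1 higher and 6 lower relative to the median gene. The median of 0.41, at percentile 0.4, turned to -0.43 relative to the median gene. The shaft keratin gene Krt35 stood at 109 against 59.7 RPKM, the transcription factor gene Dlx3 at 84.2 against 73.0 RPKM and Krtap8-1 at 49.8 against 49.1 RPKM, and all of these turned lower relative to the median gene. S100a3, a calcium-binding protein of the hair cuticle, went the other way at 79.9 against 11.6 RPKM. Hair keratins and keratin-associated proteins have close relatives that can share reads, so their single values are uncertain.

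Suprabasal and cornified epidermis genes were mixed, with 9 of 23 measured members at least 2-fold higher and 2 lower, and 2 higher and 3 lower relative to the median gene. The median of 0.48 lay at percentile 1.67 and turned to -0.19 relative to the median gene, where the percentile was 5.3. It lay at percentile 4.42 among lists not matched on expression and at 47.9 without a filter on low values. Dmkn, a secreted protein of differentiating keratinocytes, stood at 168 against 50.7 RPKM, and Krtdap, another such protein, at 19.96 against 43.8 RPKM. Lypd3 stood at 154 against 65.9 RPKM and turned lower, to -0.10, with scaling to genes outside the 50 most abundant, and Krt77 stood at 39.1 against 37.4 RPKM and turned lower relative to the median gene. Among tight and adherens junction genes 9 of 16 were at least 2-fold higher and none lower, with 3 higher and 1 lower relative to the median gene. Their median was 1.12 at percentile 78.9, and turned from 0.20 relative to the median gene to -0.13 with scaling to genes outside the 50 most abundant. F11r, which encodes the junctional adhesion molecule A, stood at 54.2 against 6.00 RPKM and stayed higher under every scaling. Cdh1, which encodes E-cadherin, stood at 38.7 against 18.5 RPKM and Ctnnd1, its binding partner p120-catenin, at 33.9 against 16.6 RPKM; they turned to -0.25 and -0.29 with scaling to genes outside the 50 most abundant.

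Sebaceous gland genes had 12 of 16 measured members at least 2-fold higher and 1 lower, with 6 higher and 2 lower relative to the median gene. The median was 1.27 at percentile 89.7, and at 97.9 with a pseudocount of 5, or 0.42 relative to the median gene, at percentile 75.3. In ZIP10-negative cells 2 members were listed at 0 and in ZIP10-positive cells 1, and 10 of the other 13 were at least 2-fold higher. Fabp5, a fatty acid-binding protein, stood at 686 against 109.7 RPKM and Mgst1, a glutathione transferase, at 379 against 74.2 RPKM. Mc5r, a melanocortin receptor, stood at 46.1 against 19.2 RPKM and turned to -0.063 with scaling to genes outside the 50 most abundant. In the adipocyte list 5 of 8 were at least 2-fold higher and none lower, and relative to the median gene 3 were higher and 2 lower, with a median of 1.37 at percentile 94.9. Fabp4, a fatty acid-binding protein of fat cells, stood at 104 against 20.2 RPKM, while Fasn, fatty acid synthase, stood at 10.3 against 17.6 RPKM.

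Medians of dermal cell genes lay below most random lists of similar expression, which were not matched on transcript length. Of 27 measured dermal fibroblast genes 7 were at least 2-fold higher and 1 lower as deposited, and 3 higher and 7 lower relative to the median gene. The median of 0.19, at percentile 0.01, turned to -0.69 relative to the median gene. The intermediate filament gene Vim stood at 478 against 475 RPKM, Sparc at 245 against 280.3 RPKM, and the collagen genes Col1a1 and Col3a1 at 97.9 and 133 RPKM against 168 and 121 RPKM; Vim and Col3a1 turned lower relative to the median gene. Dermal papilla and sheath genes had 6 of 22 at least 2-fold higher and none lower, but 2 higher and 6 lower relative to the median gene. Their median of 0.53, at percentile 0.3 but 6.76 among lists not matched on expression, turned to -0.35 relative to the median gene. Wif1, a WNT inhibitor, stood at 700.1 against 401 RPKM but lower relative to the median gene, and Corin, a protease of the dermal papilla, at 69.7 against 73.9 RPKM. Crabp1, which binds retinoic acid, stood at 659 against 163 RPKM and was 2-fold higher relative to the median gene too, but not with scaling to genes outside the 50 most abundant, at a log2 ratio of 0.69. Pericyte and smooth muscle genes had 2 of 11 at least 2-fold higher and none lower, and none higher and 3 lower relative to the median gene. Their median of 0.12, at percentile 1.35, turned to -0.53 relative to the median gene, where the percentile was 3.34, and without a filter on low values it was 2.79. Acta2, smooth muscle actin, stood at 47.9 against 16.8 RPKM and the pericyte gene Rgs5 at 14.1 against 15.4 RPKM.

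Melanocyte genes had 1 of 17 members at least 2-fold higher and 1 lower, and none higher and 5 lower relative to the median gene. Their median of 0.033, at percentile 0.03, turned to -0.71 relative to the median gene. By any amount, 15 of the 17 members lay below the median gene and 2 above. The pigment genes Dct, Pmel and Mlana stood at 118, 79.4 and 53.1 RPKM against 73.3, 53.5 and 33.0 RPKM, all below the median gene. Cd63, a membrane protein of many cell types, was the member at least 2-fold higher, at 382 against 121 RPKM. Schwann cell and nerve genes had 1 of 11 higher and none lower, with a median of 0.27 at percentile 6.1 that turned to -0.37 relative to the median gene. There 1 of these genes was at least 2-fold higher and 1 lower, while 9 of the 11 lay below the median gene by any amount. Their most abundant member, the myelin gene Pmp22, stood at 30.1 against 18.3 RPKM and turned lower relative to the median gene. Endothelial genes had 4 of 9 higher and none lower, with a median of 0.82 at percentile 54.2 that turned to -0.023 when globin genes and Rn45s were left out of the scaling. Of these 9, 1 was at least 2-fold higher and none 2-fold lower relative to the median gene, while 3 lay below it by any amount. In ZIP10-negative cells 3 of the 9 were listed at 0, and of the 6 above 0 in both libraries 1 was at least 2-fold higher as deposited. Egfl7, a secreted endothelial factor, stood at 16.5 against 0.321 RPKM and Eng at 7.23 against 7.52 RPKM. Skeletal muscle genes had 5 of 11 higher and none lower, with a median of 0.67 at percentile 52.1 and 2 higher and 1 lower relative to the median gene. That median, taken relative to the median gene, turned from 0.17 to -0.095 with scaling to genes outside the 50 most abundant. Acta1, skeletal actin, stood at 53.9 against 22.97 RPKM and also turned to -0.095 there.

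Among zinc transporters of the Slc39 family, which bring zinc into the cytosol, 6 of 11 measured members were at least 2-fold higher and 1 lower. The 6 include Slc39a10, which encodes the sorted protein and is not a finding, and the list median includes it too. Relative to the median gene, Slc39a10 and Slc39a8 were at least 2-fold higher and Slc39a4 lower, but with scaling to genes outside the 50 most abundant Slc39a10 and Slc39a8, both at 0.79, were less than 2-fold higher. Slc39a8 stood at 8.75 against 1.75 RPKM, and Slc39a4 was listed at 0 in ZIP10-positive cells against 1.27 RPKM, about 8 reads, so that its call rests on a 0 that can be a failed estimate. The more abundant Slc39a1 and Slc39a7 stood at 66.5 and 48.4 RPKM against 26.7 and 32.5 RPKM, and they turned to -0.0099 and -0.74 with scaling to genes outside the 50 most abundant. The median of the list was 1.19 at percentile 80.3, and turned from 0.33 relative to the median gene to -0.0099 under that scaling. Slc39a6, Slc39a11, Slc39a14 and Slc39a9 stood at 27.7, 13.3, 12.9 and 10.9 RPKM against 15.51, 3.66, 5.07 and 3.08 RPKM, and Slc39a6 and Slc39a14 turned to -0.53 and -0.044 when globin genes and Rn45s were left out of the scaling. Slc39a3 and Slc39a13 stood at 8.05 and 3.30 RPKM against 4.07 and 1.42 RPKM, and turned to -0.35 and -0.12 there.

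Among zinc exporters of the Slc30 family and metallothioneins, which bind zinc, 5 of 10 were at least 2-fold higher and none lower. Relative to the median gene Mt1, Mt2, Mt4 and Slc30a1 were at least 2-fold higher and none was 2-fold lower. By any amount, 7 of the 10 lay above the median gene and 3 below. Mt2 stood at 789.9 against 163 RPKM, Mt1 at 597 against 149 RPKM, Mt4 at 109.5 against 21.7 RPKM and the exporter gene Slc30a1 at 30.2 against 6.67 RPKM, and each stayed above 0 under every scaling tried. With scaling to genes outside the 50 most abundant, however, none of them was 2-fold higher, at log2 ratios of 0.94, 0.67, 0.99 and 0.80. The list median was 1.09 at percentile 62.2, and at 98.8 with a minimum of 5 RPKM, or 0.43 relative to the median gene. Slc30a5, Slc30a6 and Slc30a9 stood at 15.7, 10.1 and 6.27 RPKM against 7.42, 5.66 and 3.56 RPKM, and these, Slc30a4 and Slc30a7 turned lower with scaling to genes outside the 50 most abundant. Slc30a4 and Slc30a7 stood at 4.77 and 2.02 RPKM against 3.003 and 1.02 RPKM, and Mtf1, the zinc-sensing transcription factor, at 1.98 against 0.297 RPKM.

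Histone acetyltransferase genes lay at the median gene: 3 of 11 were at least 2-fold higher and none lower, and relative to the median gene none was 2-fold apart. The median was 0.84 at percentile 49.8, and turned from 0.080 relative to the median gene to -0.21 with scaling to genes outside the 50 most abundant. Kat2a stood at 13.9 against 13.6 RPKM and Kat5 at 15.2 against 8.01 RPKM, and they turned to -1.21 and -0.37 under that scaling. Naa50 stood at 33.0 against 13.8 RPKM and turned to -0.065 under that scaling, and Hat1 stood at 26.96 against 9.66 RPKM. Genes of WNT, SHH, BMP and Notch signalling had 7 of 29 at least 2-fold higher and none lower, and 1 higher and 3 lower relative to the median gene. Their median of 0.67, at percentile 7.14 but 0.84 with a pseudocount of 5 and 2.47 with a minimum of 5 RPKM, turned to -0.17 relative to the median gene. Id3, an inhibitor of DNA binding induced by BMP, stood at 193 against 53.6 RPKM and Sfrp1, a WNT antagonist, at 173 against 161 RPKM. Bmp4 stood at 73.7 against 37.5 RPKM; Sfrp1 and Bmp4 were among the genes that turned lower with scaling to genes outside the 50 most abundant.

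Proliferation genes had 18 of 28 members at least 2-fold higher and 1 lower, and 5 higher and 2 lower relative to the median gene. The median was 1.27 at percentile 94.5, or 0.48 relative to the median gene at percentile 97.2, and lay at percentile 98.4 with scaling to genes outside the 50 most abundant. Pcna, the DNA polymerase clamp, stood at 287 against 85.1 RPKM and Ube2c at 54.9 against 48.1 RPKM, which turned to -1.12 under that scaling. Tk1 stood at 78.6 against 37.3 RPKM and Birc5 at 50.3 against 19.7 RPKM; Tk1 turned to -0.25 with scaling to genes outside the 50 most abundant, and Birc5 to -0.044 when globin genes and Rn45s were left out. Ribosomal protein genes were at least 2-fold higher in 33 of 34 members and lower in none, and in 15 relative to the median gene. Their median was 1.94, or 0.97 relative to the median gene, at percentile 99.9. Rps18 stood at 5959 against 1120 RPKM and Rpl28 at 6277 against 2106 RPKM, though ribosomal protein genes have pseudogenes that can share reads. Genes of dissociation stress and the immediate early response had 10 of 24 members at least 2-fold higher and none lower, and 2 higher and 3 lower relative to the median gene. Their median was 0.96 at percentile 28.0, and turned from 0.040 relative to the median gene to -0.29 with scaling to genes outside the 50 most abundant. The heat shock gene Hspa8 stood at 837 against 293 RPKM. Junb stood at 64.97 against 27.9 RPKM and turned to -0.11 under that scaling.

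**Figure D2:**
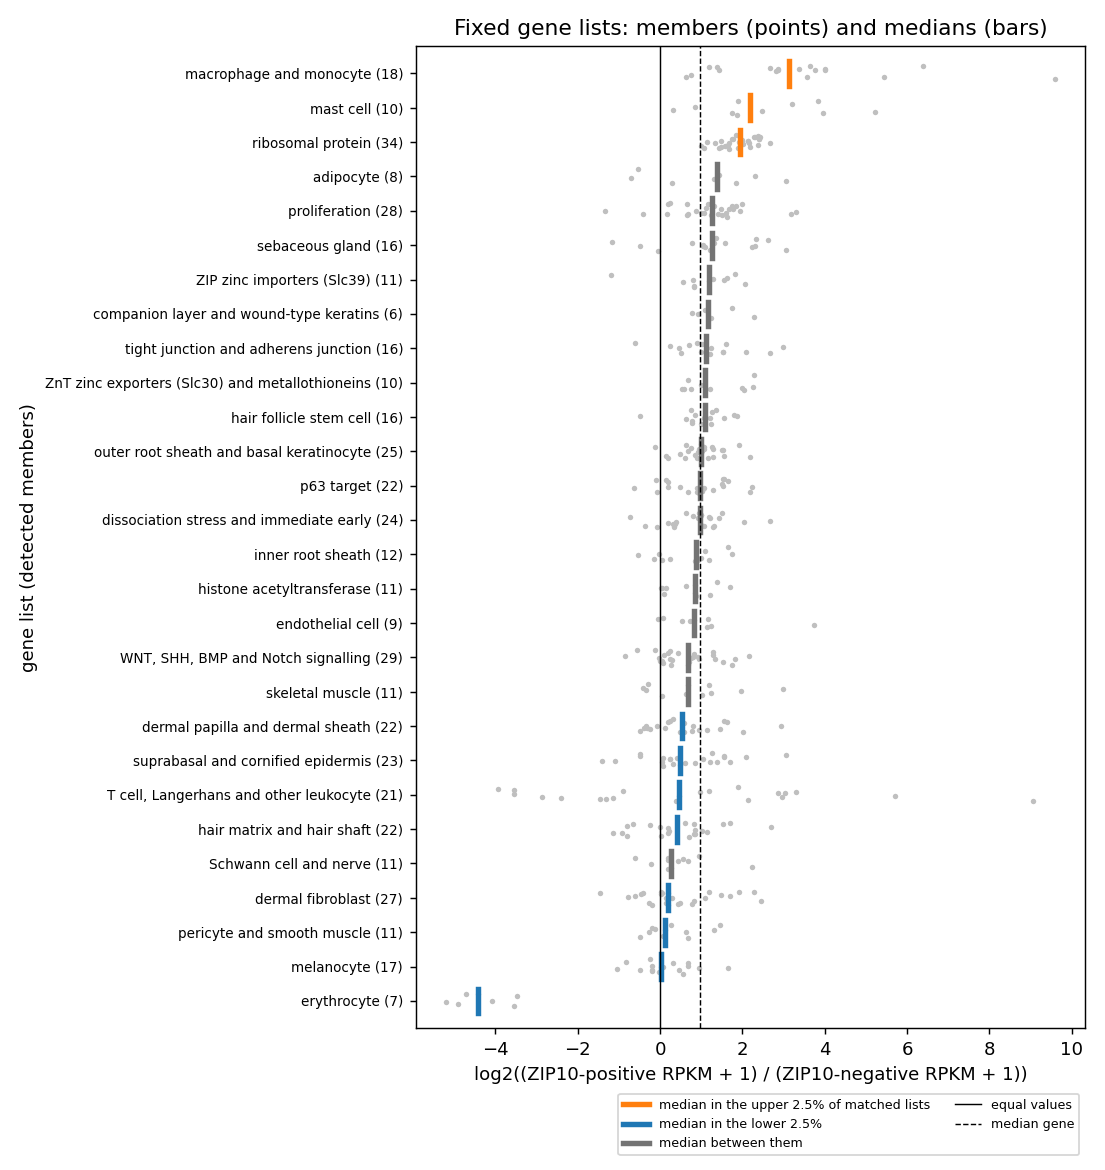
Log2 ratio of ZIP10-positive over ZIP10-negative values, each as RPKM + 1, for the 28 gene lists, with the number of measured members in brackets, members as points and medians as bars; the solid line marks equal values and the dashed line the median gene. The macrophage, mast cell and ribosomal protein medians (orange) lie in the upper 2.5% of matched lists and 8 medians (blue) in the lower 2.5%, of which all but the erythrocyte median are above 0 as deposited and below 0 relative to the median gene.

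Of the 28 lists, 3 had medians in the upper 2.5% of matched lists, 8 in the lower 2.5% and 17 between them. If members of a list varied like randomly drawn genes, 1.4 lists would be expected outside. Genes of a cell type can vary together, so that number is no measure of chance here. Log2 ratios were also lower for longer transcripts, at a Spearman's rho of -0.32 across 12095 genes, and these random lists were not matched on length. Length was examined for the ribosomal protein list only, so its part in the other percentiles was not tested. The adipocyte, skeletal muscle, junction, suprabasal and fibroblast lists each held 1 member listed at 0 in ZIP10-negative cells, which counts as higher there.

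The largest single differences were mainly entries for small RNAs. Of the 24 genes with the highest or lowest ratios, 17 were microRNA or small nucleolar RNA entries, such as Mir762, at 3299 RPKM against a listed 0, and Snord38a, at a listed 0 against 5949 RPKM. Of these 17 entries 16 were listed at 0 in the other library; short entries reach high RPKM from few reads, and reads of a host gene can be counted in them. The others among the highest were Lyz2 and S100a9. The others among the lowest included Rsad2, Slc4a1, Fam46c and Alas2. Slc4a1, the anion exchanger of the red cell membrane, stood at 0.909 against 68.8 RPKM, and Alas2, the erythroid enzyme that starts heme synthesis, at 56.2 against 1718 RPKM. Rsad2, an interferon-induced antiviral gene, stood at 0.903 against 69.5 RPKM and Fam46c at 5.12 against 194 RPKM. With small RNA entries left out, a ranking chosen after the data were seen, the highest genes included Plac8, at 399 against 0.748 RPKM, and the granule protein genes Ngp and Camp, at 127 and 106 RPKM against a listed 0. The lowest then included Isg20, an interferon-induced exonuclease, at 8.17 against 265 RPKM, and Bpgm, a red cell enzyme, at 22.5 against 561 RPKM.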

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

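Scalings to the sum without globin genes and Rn45s and counts without small RNA entries were chosen after the data were seen; the other alternatives were fixed before the data were examined. No paired analysis was possible because each group holds 1 library and no result comes from a test. The alternative for several rows of a symbol was not run, as each symbol occurs once. No spread between replicates could be measured. The scaling moves the zero point by 0.98, 1.33 or 1.39 on the log2 scale against a size rule of 1. At 1 RPKM on a 2000-base transcript, a value rests on 4.88 reads, so low genes carry wide counting error.

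The counts as deposited were 5405 higher and 435 lower. The lower count was 679 with a pseudocount of 0.1, 168 with a minimum of 5 RPKM and 288 with genes above 0 in both libraries. A pseudocount of 5 gave 2782 higher and 104 lower, and the 4-fold rule 1200 and 98. Scaling to the median gene gave 1799 and 1398, scaling to the sum outside the 50 most abundant genes 1188 and 2151, and leaving globin genes and Rn45s out of the sum 1101 and 2352. A pseudocount that damps or spreads low ratios, fewer genes under a filter, a stricter rule and a moved zero point account for these by construction.

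Scaled to the median gene, 7 called list medians changed sign: -0.43 hair matrix and shaft, -0.19 suprabasal, -0.69 fibroblast, -0.35 dermal papilla, -0.53 pericyte, -0.51 T cell and other leukocyte, and -0.71 melanocyte. Another 15 medians moved: 0.15 outer root sheath, 0.28 stem cell, 0.21 companion layer, -0.027 inner root sheath, 0.20 junction, 0.42 sebaceous, -0.37 Schwann cell, -5.40 erythrocyte, 0.33 Slc39, 0.43 Slc30 and metallothionein, 0.10 p63 target, 0.48 proliferation, 0.040 dissociation stress, 0.97 ribosomal protein, and -0.17 signalling. The percentile was 5.3 for the suprabasal and 3.34 for the pericyte list, both no longer below 2.5.

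Scaled to the sum outside the 50 most abundant genes, the same 7 called medians changed sign: -0.73 hair matrix and shaft, -0.48 suprabasal, -1.01 fibroblast, -0.68 dermal papilla, -0.81 pericyte, -0.85 T cell and other leukocyte, and -0.87 melanocyte. Another 17 moved: -0.15 outer root sheath, 0.020 stem cell, -0.12 companion layer, -0.35 inner root sheath, -0.13 junction, 0.14 sebaceous, 0.018 endothelial, -0.62 Schwann cell, -5.75 erythrocyte, -0.0099 Slc39, 0.20 Slc30 and metallothionein, -0.21 histone acetyltransferase, -0.17 p63 target, 0.22 proliferation, -0.29 dissociation stress, 0.62 ribosomal protein, and -0.50 signalling. Percentiles were 6.74 suprabasal, 3.74 pericyte and 98.4 proliferation. Of the 140 named genes 52 turned from above to below 0. Of these, 12 had been at least 2-fold higher as deposited: -0.042 Krt14, -0.24 Krt15, -0.053 Krt16, -0.19 Krt75, -0.10 Lypd3, -0.25 Cdh1, -0.063 Mc5r, -0.095 Acta1, -0.0099 Slc39a1, -0.065 Naa50, -0.25 Tk1, and -0.11 Junb. The other 40 had been less than 2-fold higher. With scaling to the median gene 34 turned, none of them 2-fold higher as deposited.

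Scaled to the sum without globin genes and Rn45s, those 7 called medians changed sign too: -0.79 hair matrix and shaft, -0.53 suprabasal, -1.07 fibroblast, -0.74 dermal papilla, -0.86 pericyte, -0.92 T cell and other leukocyte, and -0.90 melanocyte. Another 17 moved: -0.21 outer root sheath, -0.031 stem cell, -0.19 companion layer, -0.41 inner root sheath, -0.20 junction, 0.091 sebaceous, -0.023 endothelial, -0.66 Schwann cell, -5.81 erythrocyte, -0.075 Slc39, 0.17 Slc30 and metallothionein, -0.26 histone acetyltransferase, -0.22 p63 target, 0.17 proliferation, -0.36 dissociation stress, 0.55 ribosomal protein, and -0.56 signalling. The skeletal muscle median, not called, turned from 0.67 to -0.16 here and to -0.095 outside the 50 most abundant genes, within its interval over members. Percentiles were 7.27 suprabasal, 3.63 pericyte and 98.5 proliferation. Of the named genes 54 turned from above to below 0, of which 14 had been at least 2-fold higher as deposited: -0.11 Krt14, -0.31 Krt15, -0.12 Krt16, -0.26 Krt75, -0.17 Lypd3, -0.31 Cdh1, -0.13 Mc5r, -0.16 Acta1, -0.075 Slc39a1, -0.044 Slc39a14, -0.13 Naa50, -0.31 Tk1, -0.044 Birc5, and -0.17 Junb. The other 40 had been less than 2-fold higher. Scaled to a sum of 1000000, the melanocyte median alone among called medians changed sign, to -0.0011, and of the named genes Kat2a, Krtap8-1 and Vim, each less than 2-fold higher as deposited. In these scalings the changes of sign follow from the moved zero point.

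With a pseudocount of 0.1 the endothelial, macrophage and mast cell medians moved to 1.27, 4.97 and 4.19, the suprabasal percentile to 5.45 and the proliferation percentile to 98.7. With a pseudocount of 5 the outer root sheath and stem cell medians moved to 0.64 and 0.62, and percentiles to 3.93 suprabasal, 97.9 sebaceous and 0.84 signalling. With a minimum of 5 RPKM the endothelial median moved to 1.84. It then rested on Egfl7 and Eng only, at log2 ratios of 3.73 and -0.050, too few for a percentile. With that minimum the pericyte median changed sign to -0.12, and percentiles moved to 98.8 Slc30 and metallothionein and 2.47 signalling. Without a filter, percentiles were 47.9 suprabasal and 2.79 pericyte. Against random lists not matched on expression they were 4.42 suprabasal, 6.76 dermal papilla, 4.71 T cell and other leukocyte and 98.0 proliferation. For these percentiles the cause was not tested. The macrophage, mast cell and ribosomal protein lists stayed in the upper 2.5% of random lists, and the hair matrix, fibroblast, melanocyte and erythrocyte lists in the lower 2.5%, under each alternative run.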

Other observations

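The tests of the shift between the libraries, of cell type shares and of Fc receptors were chosen after the result was seen; the tests of length bias and of the wider interferon programme were set before their result was seen. Further gene groups separated the populations. Neutrophil genes were higher in ZIP10-positive cells in 11 of 11 measured members, with a median log2 ratio of 2.62, or 2.22 relative to the median gene, at percentile 100; the list was written after Ngp, Camp and Lcn2 were seen, so its direction is not independent evidence. Of the 11 members 8 were listed at 0 in ZIP10-negative cells, which can be a failed estimate, and the 3 above 0 in both libraries had a median of 1.72 relative to the median gene. Ngp and Camp, granule proteins of neutrophils, stood at 127 and 106 RPKM and Lcn2 at 28.8 RPKM, each against a listed 0, while the chemokine receptor gene Cxcr2 stood at 6.52 against 0.507 RPKM. Genes of cytotoxic or gamma delta T cells and NK cells, a list written after Cd3g, Cd3e, Cd7 and Nkg7 were seen, were lower in 13 of 17 measured members and higher in 1, Gzmb, which stood at 2.96 against 0.304 RPKM. Their median was -1.63, at percentile 0, and relative to the median gene 15 of the 17 were lower. As with the neutrophil list, this direction is not independent evidence. Ncr1 was listed at 0 in ZIP10-positive cells. Ctsw, a protease of cytotoxic lymphocytes, stood at 18.2 against 129 RPKM, Itgae, an integrin of tissue-resident T cells, at 3.66 against 60.3 RPKM and Xcl1, a chemokine, at 47.0 against 80.3 RPKM. Thy1, at 38.5 against 107 RPKM, is in the dermal fibroblast list too.

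The T-lineage genes Cd2, Cd3d, Cd3e, Cd3g, Cd7 and Lck were picked from the fixed leukocyte list after their values were seen. They were lower in 6 of 6 members, with a median of -2.64, or -3.53 relative to the median gene. Because of that choice their direction is not independent evidence. Cd3e stood at 13.7 against 171 RPKM and Cd7 at 13.3 against 219 RPKM. In the same library as the T-lineage genes, the antiviral genes Rsad2 and Isg20 were high, at 69.5 and 265 RPKM. A wider interferon programme was examined as a hypothesis with 14 other measured interferon-stimulated genes. Their median of 0.60 lay at percentile 27.8, within the range of matched lists. This bound, set beforehand, was a poor one and leaves the hypothesis open, because 8 of the 14 lay under 3 RPKM in both libraries and members went both ways, with 8 above and 6 below the median gene. Relative to the median gene 1 member was at least 2-fold higher and 2 lower in ZIP10-positive cells, against 5 and 1 as deposited. The lower members were Isg15, at 6.51 against 48.0 RPKM, and Irf7, at 7.14 against 14.7 RPKM, while Bst2 stood at 28.1 against 9.83 RPKM.

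The median gene was 1.97-fold higher in the ZIP10-positive library. Globin reads made up an estimated 16.0% of reads in the ZIP10-negative and 0.952% in the ZIP10-positive library, which accounts for a log2 shift of 0.24 and leaves most of the observed 0.98, with a 95% interval of 0.964 to 1.002 over genes, so globin alone is argued against. The depth ratio of 1.03 was searched for only near equal depth, so it cannot decide on a difference in depth. RPKM values are also already scaled by library size. Reads on neither globin nor other listed genes of known length made up an estimated 56.7% in the ZIP10-negative and 39.7% in the ZIP10-positive library, and may hold ribosomal RNA, reads outside genes, or both. These cannot be told apart, since the annotation used lacks a length for Rn45s and the shares sum to 100% by construction. A difference in RNA content between the populations is untested. All these shares are rough, as they rest on median annotated lengths, such as 737 bases for Col3a1, that may be too short for some genes. Lengths that are too short would move reads of listed genes into the remainder. Of the 5 globin genes, 2 were given the length of another globin gene, Beta-s.

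Macrophage and mast cell genes were higher and T-lineage and erythrocyte genes lower in ZIP10-positive cells. A lower share of a main cell type among ZIP10-positive cells would raise genes of all other types alike. Among the lists fixed before the data were examined, fibroblast and melanocyte medians were at most 0.816 at their upper 95% bounds over members. That lay 0.61 below the lower bound of the macrophage median, 1.43. Macrophage, fibroblast and melanocyte genes were thus not raised alike in these 2 libraries. These medians were known when the comparison was chosen, so it cannot decide whether a lower share of 1 cell type was the only change. Other fixed lists, some with upper bounds above 1.43, were not part of the comparison. The bounds run over genes of 1 library per group and measure no error of cell shares. Several shares changing together, or a change in the myeloid cells, stay open. Binding of the rabbit antibody by Fc receptors is another candidate explanation. The 4 Fc gamma receptor genes had higher values, with a median of 2.54 relative to the median gene. Of these Fcgr1 and Fcgr4 were listed at 0 in ZIP10-negative cells, the others had a median of 2.38, and Fcgr3, which is in the macrophage list too, stood at 19.5 against 0.641 RPKM. ZIP10 on the same cells predicts this as well, and the labels name normal rabbit IgG as a control stain without its result, so antibody binding and ZIP10 on myeloid cells cannot be told apart.

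Ribosomal protein genes were higher relative to matched genes. Log2 ratios were lower for longer transcripts, at a Spearman's rho of -0.32 across 12095 genes, which are not independent replicates, and ribosomal transcripts had a median length of 791 bases against 2013 for all compared genes. Against random lists matched on length and expression, whose median was 1.22, the ribosomal median of 1.94 lay at percentile 100. Each gene was matched to its nearest 40 others without a limit on distance, and ribosomal protein genes were left out of these. Ribosomal values were high, with medians of 2612 and 717 RPKM in the ZIP10-positive and ZIP10-negative libraries. How close the match came was not checked, so the percentile cannot settle length bias. Shared reads with pseudogenes and a difference between the sorted populations stay open and untested.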
